A study of Mus musculus with 13 samples.

How the data were processed

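Samples were 13 mouse embryos of embryonic day 9.5. Per the labels' protocols, total RNA was extracted with RNeasy columns and treated with DNase on the column, and directional libraries were made with a NEBNext Ultra kit after poly(A) isolation. The authors deposited 1 table of FPKM values per gene and sample with a locus on the mm9 build, and per the submitters' processing notes bcl2fastq 1.8.2, TopHat and Cufflinks were used; versions of the last pair, the annotation, filters and strand settings are not given in the sources used here. FPKM is divided by transcript length and by mapped fragments, so a value holds no count and a few abundant RNAs can shift all others. Short RNAs get large FPKM from few fragments: genes of small RNA families held 12.5% to 27.3% of the summed FPKM per sample, and 285 of them were among the genes tested.

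The table holds 23217 genes, none with a repeated symbol, with values to 2 decimals; 3691 genes were listed at 0 in all samples. In 34 low genes examined the values showed no steps that would give whole reads, so the depth per sample is unknown, no interval from counts is given, and low genes are the least certain. An entry of 0 can be a failed estimate, since 69 genes with a median over 5 FPKM were listed at 0 somewhere, 60 of them small RNAs. Loci in the table are bundles that can join overlapping genes, such as Airn with Igf2r, Mest with Copg2 and Nespas with Gnas, and values of such genes, of antisense pairs and of families with near-identical copies (histones, ribosomal proteins) are uncertain. No columns were identical, and correlations between samples over tested genes ran from 0.904 to 0.953.

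Groups were taken from the genotype label. Genes with a mean FPKM of at least 1 over the 13 samples were tested, 12755 in all, on log2(FPKM+1), so fold changes are on that scale and understate the change of low genes. The group comparison used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided) without covariates, with Benjamini-Hochberg adjustment at 0.05. Lists of genes (imprinted genes by expressed copy, DNA methylation machinery, tissue and cell type markers, stress, hypoxia, p53 and cell cycle genes, replication histones, immediate early and sex-linked genes) were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry where at least 5 members were measured. Germline and macrophage lists had 1 and 2 measured members and were not tested. fry passed 0 lists. Germ-line, placental and decidual lists stand for cells the dissection could carry along.

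Medians of the imprinted lists were compared by an exact permutation test over all 286 splits of the samples into 3 and 10, whose smallest p is 0.0035. A departure is a difference of at least 1 log2 unit from the mean of the xHet embryos (of the other 2 for a xHet embryo). Departures per embryo and the SD among embryos were set beside 10000 random lists without imprinted genes, each gene drawn from its 100 nearest neighbours in mean expression. Correlations of neighbours used 100000 permutations over 10 xHomo embryos and were not computed where the largest gap between values exceeded 0.5 of their range. That bound, the upper 2.5% of matched lists as the limit, the difference of means as the summary of departures and the log2 scale for Dixon's test were set after values could be seen. So was recomputing the reference and the departures within each split of their permutation test; with the counts held fixed the p was 0.0734. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

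The limma step was tested on simulated data with the group sizes and 12755 genes of this comparison: of 50 genes planted at each size it recovered 11 at a log2 change of 0.5, 46 at 1, 50 at 2 and 49 at 3, with 8 of 164 calls not planted. The simulated noise was drawn for each gene by itself, with the same SD in both groups. In the real data genes of a list were correlated. Random matched lists there had a median SD of 0.23 among xHomo and 0.10 among xHet embryos. These rates therefore do not give the power or error rate of the real comparison. The departure step recovered 20 of 20 planted log2 changes of -2.5, set in simulated noise held to a small SD. Changes that large could hardly be missed at a threshold of 1 log2 unit. The check shows only that the step runs as written. The genes named were set by rule before the data were examined: up to 12 passing genes per direction with the largest change, filled to 6 by smallest p where fewer passed; imprinted genes passing over the list, or the 6 with the smallest p; the 10 imprinted genes with the largest SD among xHomo embryos; Tet1, Tet2, Tet3, Peg3, Peg10, Sgce, Usp29, Mest, Igf2, H19, Xist, Ddx3y and Eif2s3y; and up to 4 members with the smallest p of each list described. Genes outside the rule are said to have been chosen after their values were seen.

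Alternatives were pseudocounts of 0.1 and 5, no filter and a mean FPKM of at least 5, TPM rescaling, median-of-ratios scaling, quantile normalization, replicate number as a block, log2 Xist as a covariate, each sample left out, array weights, no trend, an exact permutation test per gene, X and Y genes left out, other thresholds and references for departures, and the median absolute deviation. Added after seeing the data were fits without small RNA genes, without xHomo embryos 3 and 9 together, and on replicates 1 to 3 without a block. Summing rows of the same symbol had nothing to sum and was not run.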

Results

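Polyadenylated RNA was sequenced from 13 mouse embryos of embryonic day 9.5, on the C57BL/6J strain background given in the labels. The labels sort the embryos into 3 called xHet and 10 called xHomo and do not spell out either name. The series concerns Tet1, an enzyme that oxidizes 5-methylcytosine, in the erasure of genomic imprints, the methylation marks that restrict a gene to its maternal or paternal copy. From what is known of the study, the embryos descend from fathers heterozygous or homozygous for a Tet1 mutation; the labels themselves do not state this. The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library) for 23217 genes. Summed FPKM ran from 543948 to 570161 in the xHet embryos and from 500126 to 662936 in the xHomo embryos, and the read depth behind them is unknown. Litters, batches and sex are not in the labels, so every p-value measures only the spread between these samples. Xist, the RNA of the inactive X chromosome, was near 0 in all 3 xHet embryos and high in 5 of 10 xHomo embryos, so the groups are not balanced for sex. Coordinates are those of the deposited table on the mm9 build, counted from 1.

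The first comparison asked which genes differed in mean level between xHomo and xHet embryos. Alad, which encodes an enzyme of heme synthesis (chromosome 4, 62170204 to 62181097), rose from 26.5 ± 0.208 FPKM (SD, n = 3) to 55.2 ± 5.98 FPKM (SD, n = 10), a log2 change of 1.02 (SE 0.10, limma adjusted p = 0.000578). Rec8, a meiotic cohesin gene (chromosome 14, 56237003 to 56244232), rose from 0.910 ± 0.0721 to 2.66 ± 0.50 FPKM, with a log2 change of 0.93 (SE 0.13, limma adjusted p = 0.0142). The transcript 4933404O12Rik (chromosome 5, 137395016 to 137412979) rose from 2.21 ± 0.226 to 4.2 ± 0.367 FPKM, with a log2 change of 0.69 (SE 0.09, limma adjusted p = 0.0140). Each of these 3 genes was higher in 10 of 10 xHomo embryos than in any xHet embryo. Of 12755 genes tested in limma these 3 passed in the higher and 0 in the lower direction, where 220 genes had an unadjusted p under 0.05.

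Genes next in line by p did not pass, and their values are given without a call. Dnajb1, a heat shock cochaperone gene, stood at 14.3 ± 2.20 FPKM in xHet and 21.8 ± 2.26 FPKM in xHomo embryos (limma adjusted p = 0.168). Gstm6, a glutathione transferase gene, stood at 0.623 ± 0.110 and 2.12 ± 0.636 FPKM, and 2810428I15Rik at 26.9 ± 1.42 and 42.3 ± 5.04 FPKM (limma adjusted p = 0.168 and 0.132). On the lower side, Hfm1, a meiotic helicase gene, stood at 1.86 ± 0.347 and 0.779 ± 0.187 FPKM (limma adjusted p = 0.168). Zfp566, a zinc finger gene, stood at 9.21 ± 0.806 and 6.31 ± 0.651 FPKM, and Dhrs11, a dehydrogenase gene, at 6.64 ± 0.959 and 4.12 ± 0.684 FPKM (limma adjusted p = 0.184 and 0.321). The small RNA genes Mir483, Snord82 and Mir130b were also on this side. Mir483 was listed at 0 in 9 of 10 xHomo embryos and at 115 FPKM in xHomo embryo 10, against 77.1, 119 and 128 FPKM in xHet embryos 1 to 3, while Snord82 and Mir130b were listed at 0 in all 10 xHomo embryos and in xHet embryo 1. Single libraries decided some of these calls: 2810428I15Rik passed without xHomo embryo 2 (limma adjusted p = 0.0241) or 3, Hfm1 without xHomo embryo 3 (0.0369), Mir483 without xHomo embryo 10 (1.4e-12), and Snord82 and Mir130b without xHet embryo 1 (1.3e-14 and 1.9e-07).

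At an unadjusted p under 0.05, 973 genes were higher in xHomo embryos. Groups did not overlap at all for 212 genes on the higher and 74 on the lower side. These are 2.24% of genes, against 0.699% expected on average over all splits of the samples. How far this share ranges between splits was not computed, so the excess is not a test of the groups. Leaving out 1 embryo kept the log2 change at 0.89 to 0.96 for Rec8 and 0.64 to 0.74 for 4933404O12Rik. The calls changed with single libraries. Rec8 was lost without xHet embryo 1 (limma adjusted p = 0.0737), Rec8 and 4933404O12Rik were lost without xHet embryo 2 (both 0.236) or xHet embryo 3 (0.134 and 0.114), and 5 genes passed without xHomo embryo 2 and 11 (10 higher and 1 lower) without xHomo embryo 3. An exact permutation test per gene passed 0 genes (smallest adjusted p = 0.388), and limma with array weights passed 2779 (2371 higher and 408 lower). With log2 Xist as a covariate only Alad passed. In xHomo embryos 1, 4, 5, 6 and 8, with Xist near 0 as in the xHet embryos, Rec8 was 2.13 to 2.90 FPKM. There 4933404O12Rik was 3.70 to 4.69 FPKM. The xHet embryos had 0.85 to 0.99 and 1.96 to 2.40 FPKM of these genes.

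**Figure D1:**
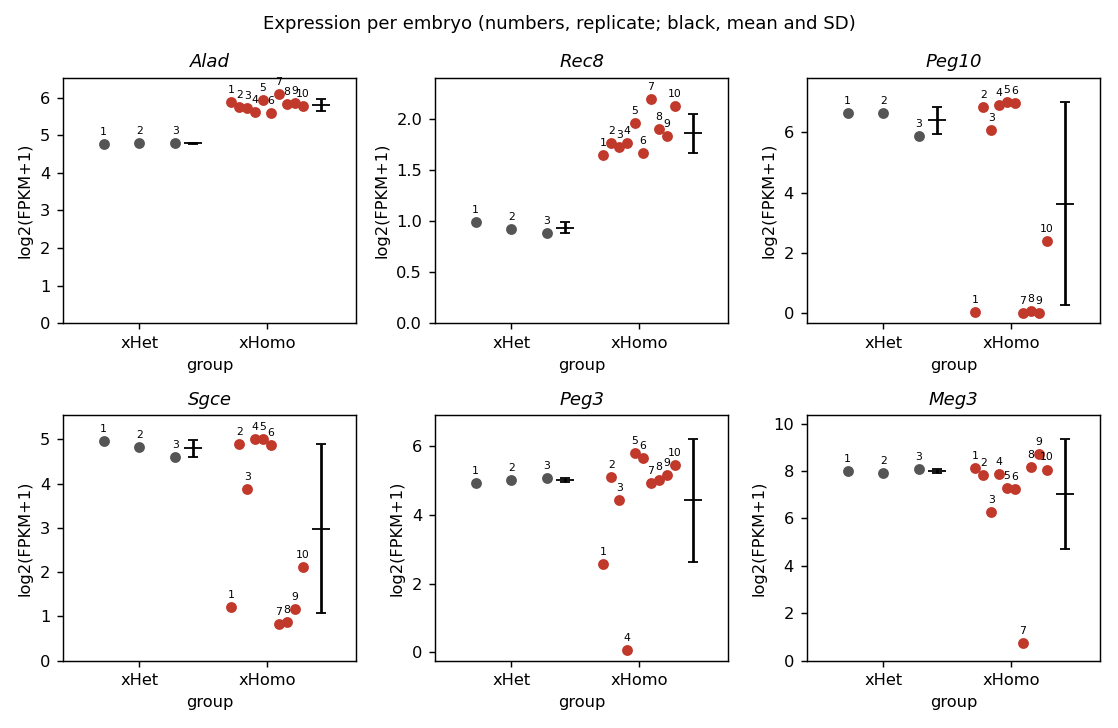
Expression of Alad, Rec8, Peg10, Sgce, Peg3 and Meg3 per embryo as log2(FPKM+1) on the vertical axis, by group on the horizontal axis; each point is 1 embryo with its replicate number, and black bars give the mean and SD of each group. Alad and Rec8 are higher in all 10 xHomo embryos, while Peg10 and Sgce split the xHomo embryos, with embryos 1, 7, 8, 9 and 10 low.

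The dioxygenase genes themselves were compared next. Tet1 stood at 2.35 ± 0.367 FPKM in the xHet and 2.15 ± 0.543 FPKM in the xHomo embryos (log2 change -0.10, SE 0.16, limma adjusted p = 0.863), with single values of 2.61, 1.93 and 2.51 FPKM in xHet embryos 1 to 3 and 1.11 to 2.87 FPKM in the xHomo embryos. Tet2 stood at 3.51 ± 0.218 and 3.75 ± 1.35 FPKM (limma adjusted p = 0.978), and Tet3 at 8.70 ± 0.165 and 9.27 ± 1.83 FPKM (limma adjusted p = 0.925). The sign of the Tet2 difference turned under all 3 rescalings and that of Tet3 under TPM rescaling.

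Whether imprinted genes shifted as a group was asked with 54 measured genes of 2 lists fixed beforehand, 26 listed as expressed from the paternal and 28 from the maternal copy. The deposited values do not separate the copies. Whether each listed gene was expressed from 1 copy in these embryos was therefore not measured. None of the 54 genes passed, adjusted over the list alone or over all genes tested. An unadjusted p under 0.05 in limma was found for 8, 7 of them higher in xHomo embryos. The 6 with the smallest p each had a limma adjusted p of 0.232 over the list alone. Grb10, a maternally expressed adaptor that restrains growth, stood at 214 ± 5.76 FPKM in xHet and 368 ± 133 FPKM in xHomo embryos. Cdkn1c, a maternally expressed inhibitor of cyclin-dependent kinases, stood at 69.8 ± 4.04 and 107 ± 32.6 FPKM. H19, a maternally expressed noncoding RNA, stood at 497 ± 23.1 and 669 ± 119 FPKM, and its neighbour Igf2 at 432 ± 13.5 and 466 ± 68.1 FPKM. Asb4 stood at 22.0 ± 3.65 and 31.8 ± 6.59 FPKM, and Ube3a, a ubiquitin ligase gene, at 7.32 ± 1.28 and 10.1 ± 1.83 FPKM. Tspan32 stood at 2.84 ± 0.483 and 1.68 ± 0.643 FPKM. With array weights, 14 imprinted genes passed over the list alone.

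The median log2 change of the 26 paternally expressed genes was -0.12, with 11 higher and 15 lower (exact permutation test over 286 splits, two-sided, p = 0.248). That of the 28 maternally expressed genes was 0.08, with 16 higher and 12 lower (exact permutation p = 0.423), while their mean was -0.0027. For the paternally expressed genes the median passed the same exact test after median-of-ratios scaling (-0.16, p = 0.0035, the smallest p the design allows) and after quantile normalization (-0.14, p = 0.0140). It did not pass after TPM rescaling (-0.15, exact permutation p = 0.0874), and its sign turned with no filter on low values (0.00024, p = 0.997) and with the Xist covariate (0.018, p = 0.857).

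The next question was whether single xHomo embryos departed at different imprinted genes, which a group mean would hide. The plainest case was Peg10, a retrotransposon-derived gene expressed from the paternal copy (chromosome 6, 4697306 to 4710516), and its neighbour Sgce, which encodes epsilon-sarcoglycan (chromosome 6, 4624350 to 4697204). Peg10 stood at 99.8, 99.7 and 57.8 FPKM in xHet embryos 1 to 3. In xHomo embryos 1, 7, 8, 9 and 10 it was 0.03, 0.01, 0.05, 0.01 and 4.19 FPKM, and in the other 5 xHomo embryos 66.8 to 126.9 FPKM. Sgce stood at 27.0 ± 3.58 FPKM in xHet embryos and at 1.31, 0.77, 0.83, 1.23 and 3.33 FPKM in xHomo embryos 1, 7, 8, 9 and 10. As group means neither passed in limma (adjusted p = 0.628 for Peg10 and 0.578 for Sgce).

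Other imprinted domains departed as well, in part in the same embryos. Peg3, a paternally expressed zinc finger gene (chromosome 7, 6658671 to 6683130), stood at 31.2 ± 1.46 FPKM in xHet embryos, at 0.05 FPKM in xHomo embryo 4 and at 4.99 FPKM in xHomo embryo 1. Its neighbour Usp29, below the filter on low values, was 0.02 and 0.10 FPKM in these embryos against 0.523 ± 0.0513 FPKM in xHet embryos, and the maternally expressed Zim1 was 10.2 and 6.29 FPKM against 3.42 ± 0.546 FPKM. Zim1 was also 5.86 FPKM in xHomo embryo 10, where Peg3 was 42.5 FPKM. In xHomo embryo 7 the maternally expressed noncoding RNAs Meg3, Rian and Mirg of chromosome 12 were 0.69, 3.18 and 1.17 FPKM, against 255 ± 14.2, 200.1 ± 6.49 and 34.6 ± 3.0 FPKM in xHet embryos. In xHomo embryo 3 they were 75.6, 94.4 and 12 FPKM. There 10.2% of all genes departed, so falls in that embryo may not be particular to imprinted genes. Dlk1 of the same domain, chosen after its values were seen, was 299 FPKM in xHomo embryo 7 and 80.2 FPKM in xHomo embryo 3 against 162 ± 18.8 FPKM. Nnat, which encodes neuronatin, was 27.3 FPKM in xHomo embryo 5 against 352 ± 34.7 FPKM in xHet embryos, and Mest was 296 FPKM in xHomo embryo 9 against 1053 ± 77.8 FPKM. Impact, a paternally expressed regulator of translation, was 4.94, 6.48 and 5.63 FPKM in xHomo embryos 3, 5 and 10 against 20.1 ± 1.61 FPKM.

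Airn, the antisense RNA that overlaps Igf2r on chromosome 17, varied within both groups. It was 5.38, 11 and 0 FPKM in xHet embryos 1 to 3, the last value being listed at 0, and Igf2r was 119 FPKM in xHet embryo 3 against 56.5 FPKM at the lowest in that group. Airn was 0.13 FPKM in xHomo embryo 1 and listed at 0 in xHomo embryo 7, where Igf2r stood at 110 FPKM. Grb10 was at least 2-fold above the xHet mean in xHomo embryos 2, 4, 6 and 9 (436, 527, 576 and 500.2 FPKM). Strand use in the quantification is not stated, so reads of overlapping antisense pairs such as Airn and Igf2r may have been shared.

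**Figure D2:**
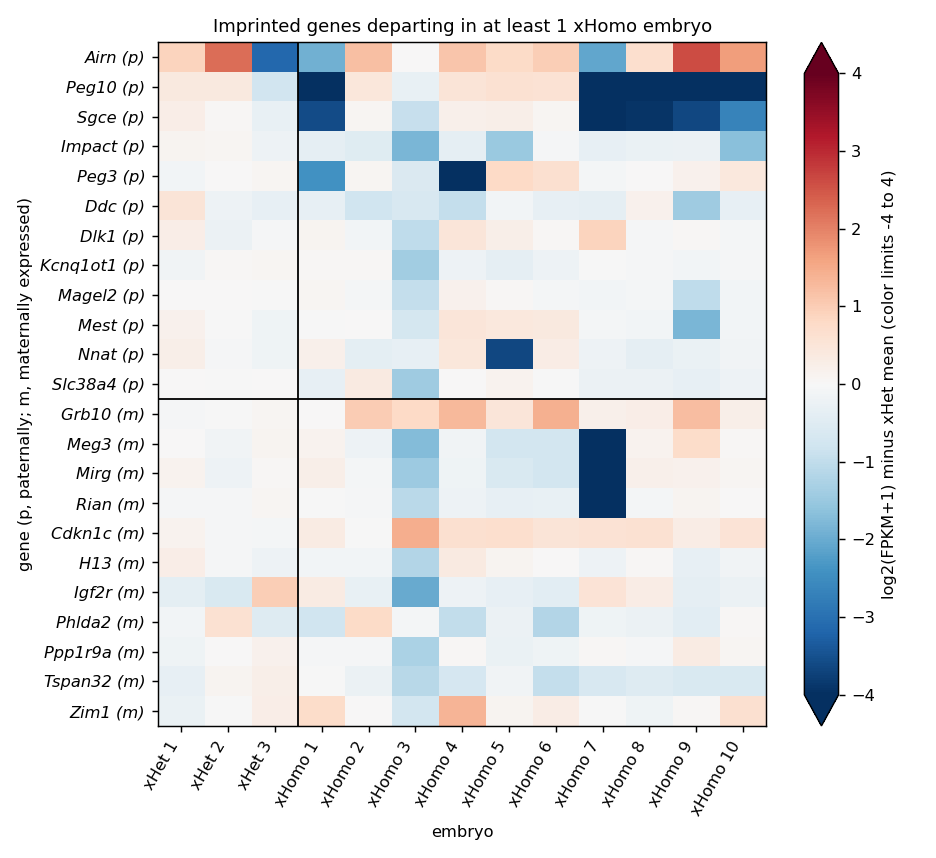
Difference of log2(FPKM+1) from the xHet mean (color, cut at -4 and 4) for the 23 imprinted genes that departed by at least 1 log2 unit in at least 1 xHomo embryo; columns are embryos, a xHet embryo is set against the mean of the other 2, and rows are paternally (p) or maternally (m) expressed genes. Peg10 and Sgce are low in xHomo embryos 1, 7, 8, 9 and 10, Peg3 in 1 and 4, and Meg3, Rian and Mirg in 3 and 7. In xHomo embryo 3, 10.2% of all genes departed as far.

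Counted over all 54 imprinted genes, xHet embryos 1 to 3 had 0, 1 and 1 genes at least 1 log2 unit from the xHet mean. The xHomo embryos 1 to 10 had 4, 2, 12, 4, 2, 2, 6, 2, 7 and 4 such genes. The mean was 4.50 ± 3.17 (SD, n = 10) against 0.667 ± 0.577 (SD, n = 3), a difference of 3.83 with p = 0.0769 in a two-sided exact permutation test that recomputed the reference for each of 286 splits. All genes departed more in xHomo embryos too, 1.45% to 10.2% of them against 1.09% to 1.14% in xHet embryos, so this difference by itself does not set imprinted genes apart. In 5 of 10 xHomo embryos (1, 3, 4, 7 and 10) and 0 of 3 xHet embryos the count was above all but the highest 2.5% of 10000 random lists matched on expression, a limit set after the values could be seen. That number was 9 without small RNA genes, added after seeing the data, 3 at a 3-fold threshold and 2 with a pseudocount of 5. In xHomo embryos 1, 4 and 10 the count was 4 against a bound of 3. Airn was among the 4 in each, so these embryos lie above the bound only with Airn. Airn also departed in xHomo embryo 7 and was the only gene departing in xHet embryos 2 and 3. Of the 45 departures among xHomo embryos 35 were lower and 10 higher, and the paternally expressed genes held 24 of the lower and 4 of the higher ones. All 4 of these higher ones were Airn. The neighbours Peg10 and Sgce gave 5 lower ones each, in the same 5 embryos, and in xHomo embryo 3 11 of 12 departures were lower. These counts are not independent, so they do not show a difference between paternally and maternally expressed genes. Without xHomo embryo 3, which had the largest share of all genes departing, the difference was 3.0 (exact permutation p = 0.0091). Without xHet embryo 1, 2 or 3 it was 2.80, 3.90 or 4.60 (exact permutation p = 0.409, 0.227 or 0.182), and without xHet embryo 1 the xHet mean was 2 departures.

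**Figure D3:**
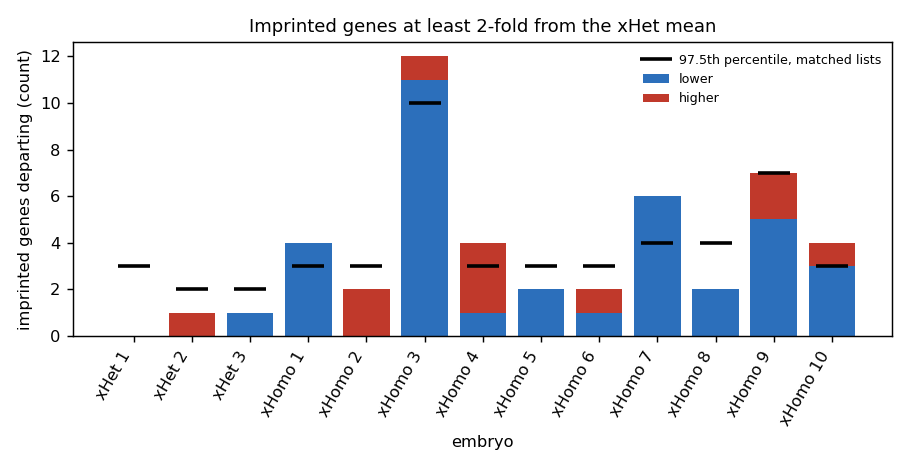
Number of imprinted genes at least 1 log2 unit (2-fold on the log2(FPKM+1) scale) below (blue) or above (red) the xHet mean in each embryo, with a black bar at the bound of the highest 2.5% of matched random lists. The xHomo embryos 1, 3, 4, 7 and 10 lie above their bar, and xHomo embryo 9 lies on it with 7 genes.

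Imprinted genes also spread more between xHomo embryos than other genes of like expression. The median SD of log2(FPKM+1) was 0.33 among the 10 xHomo embryos, above all 10000 matched lists (median 0.23, with 0.27 as the bound of the highest 2.5%), and 0.10 among the 3 xHet embryos (percentile 62.0). Peg10 had the largest SD of the imprinted genes, and 14.8% of imprinted genes against 2.11% of all genes had an SD above 1. With the median absolute deviation in place of the SD, which gives less weight to single embryos, the percentile was 84.2. The matched lists were drawn gene by gene, while imprinted genes share domains in which neighbours can depart together, as Peg10 and Sgce did. Such lists may range too narrowly, so the percentiles here and for the departure counts describe and do not test.

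Neighbouring imprinted genes were then compared across the 10 xHomo embryos. Of 13 pairs fixed beforehand, 1 was not measured and 8, among them Peg10 with Sgce and Meg3 with Rian, had values in separate clusters, so no pooled correlation was taken. Of the other 4 pairs 0 passed after adjustment and 1 had an unadjusted permutation p under 0.05. Grb10 and Ddc gave Pearson r = -0.652 (permutation p = 0.0393, adjusted p = 0.157) and Spearman rho = -0.552 (permutation p = 0.104, adjusted p = 0.308), with r = -0.818 without the 2 embryos farthest from the Grb10 median. Without xHomo embryo 6 this pair passed (r = -0.832, permutation adjusted p = 0.0180), and without xHomo embryo 5 Nnat and Blcap could be tested and passed (r = 0.851, permutation adjusted p = 0.0249). H19 and Igf2 gave r = 0.295 (permutation p = 0.440, adjusted p = 0.645) and rho = 0.491 (permutation p = 0.154, adjusted p = 0.308), with r = 0.0654 on leaving out 2 embryos likewise and r = 0.698 without xHomo embryo 3 (permutation adjusted p = 0.171). The pairs Snrpn with Ndn and Zrsr1 with Commd1 gave r = -0.252 (permutation p = 0.484) and 0.0793 (permutation p = 0.827), rho = -0.115 (permutation p = 0.760) and -0.0667 (permutation p = 0.864), and r = -0.485 and 0.0274 without 2 embryos.

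Gene groups fixed beforehand were compared between the embryo groups to describe the tissue and the libraries. In camera with a preset correlation 12 of 22 lists passed, 8 in the higher and 4 in the lower direction, and with an estimated correlation 0 passed. Replication-dependent histone genes, whose messages mostly lack a poly(A) tail and which were listed as a sign of poly(A) selection and RNA quality, were higher in 14 of 14 members (adjusted p = 0.000281, and adjusted p = 0.662 with an estimated correlation). Of these Hist1h4d and Hist1h2ab passed adjusted over the list alone and 0 over all genes. Hist1h4d stood at 5.70 ± 1.69 FPKM in xHet and 11.1 ± 2.19 FPKM in xHomo embryos, and Hist1h2ab at 4.26 ± 0.318 and 8.06 ± 2.20 FPKM. By embryo the list median was 0.10 to 1.23 log2 units above the xHet mean in xHomo and -0.21 to 0.25 in xHet embryos. In xHomo embryos 2, 3, 4 and 6 it lay within the xHet range. Whether this list reflects library quality here was not tested, so a difference between libraries may also enter the lists below. Limb bud genes were also higher in 14 of 14 members (adjusted p = 0.00417, and adjusted p = 0.662 with an estimated correlation), with the homeobox gene Msx1 at 7.50 ± 0.547 and 11.5 ± 2.73 FPKM and Msx2 at 8.68 ± 0.532 and 11.9 ± 2.23 FPKM. Hypoxia response genes were higher in 24 of 25 members, with a median log2 change of 0.52 (adjusted p = 0.00417, and adjusted p = 0.700 with an estimated correlation). Among them Eno1 and Gapdh of glycolysis stood at 126 ± 12.6 and 185 ± 42.7 FPKM and at 1636 ± 122 and 2382 ± 550 FPKM. By embryo, the median over this list was 0.52, 1.11, 1.32, 1.55 and 0.96 log2 units above the xHet mean in xHomo embryos 1, 7, 8, 9 and 10, and -0.29 to 0.08 in the other 5. Hk2 stood at 17.6 ± 2.53 and 31.7 ± 15 FPKM and Higd1a at 21.5 ± 2.07 and 35.7 ± 16.0 FPKM.

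Beside the higher histone list, immediate early genes were higher in 10 of 12 members (adjusted p = 0.0222, and adjusted p = 0.662 with an estimated correlation), and 2 of them, Ier2 at 30.0 ± 1.32 and 38.9 ± 2.79 FPKM and Jun at 12.1 ± 1.17 and 16.9 ± 1.81 FPKM, passed adjusted over the list alone and 0 over all genes. Without xHomo embryo 3, Ier2 passed over all genes (limma adjusted p = 0.0427), as did Hist1h4d of the histone list. Neuron genes were higher in 12 of 14 members (adjusted p = 0.0292, and adjusted p = 0.700 with an estimated correlation), with the growth cone gene Gap43 at 18.7 ± 0.654 and 25 ± 3.62 FPKM and the neurofilament gene Nefm at 5.75 ± 0.0889 and 9.98 ± 3.01 FPKM. Heart genes were higher in 14 of 16 members (adjusted p = 0.0298, and adjusted p = 0.662 with an estimated correlation). The myosin light chain gene Myl2 passed adjusted over the list alone, not over all genes, at 65.5 ± 3.79 and 95.8 ± 13.6 FPKM, and Myl4 stood at 75.5 ± 7.25 and 98.3 ± 16.5 FPKM. Neural crest genes (11 of 12 higher, adjusted p = 0.0400) and p53 targets (17 of 23 higher, adjusted p = 0.0462) each had adjusted p = 0.662 with an estimated correlation. Sox9 stood at 11.6 ± 0.556 and 15.7 ± 2.40 FPKM, Dlx5 at 3.78 ± 0.180 and 4.85 ± 0.567 FPKM, Cdkn1a at 3.08 ± 0.472 and 5.02 ± 1.33 FPKM and Phlda3 at 4.58 ± 0.452 and 6.24 ± 0.910 FPKM.

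In the lower direction, in the same libraries, endothelial genes were lower in 12 of 14 members, with a median log2 change of -0.23 (adjusted p = 0.0122, and adjusted p = 0.662 with an estimated correlation). Plvap stood at 56.9 ± 2.06 and 42.9 ± 10.4 FPKM and the cadherin gene Cdh5 at 36.9 ± 2.55 and 27.9 ± 6.71 FPKM, with the list median at -1.24 in xHomo embryo 3 and -0.33 to 0.0050 in the other xHomo embryos, while Sox7 stood at 2.08 ± 0.0862 and 3.23 ± 0.823 FPKM. Primitive erythroid genes were lower in 10 of 15 members (adjusted p = 0.0346, and adjusted p = 0.700 with an estimated correlation), with the receptor gene Epor at 5.55 ± 0.435 and 4.65 ± 1.62 FPKM and Alas2 of heme synthesis at 20.5 ± 1.57 and 17.9 ± 4.65 FPKM. Paternally expressed imprinted genes passed as a list (adjusted p = 0.0281, and adjusted p = 0.662 with an estimated correlation). The 5 sex-linked genes passed as well (adjusted p = 0.0283, and adjusted p = 0.662 with an estimated correlation). Xist was 0.05 to 0.08 FPKM in the xHet embryos and 112, 30.5, 122, 159 and 137 FPKM in xHomo embryos 2, 3, 7, 9 and 10, where the Y-linked genes Ddx3y and Eif2s3y were at most 0.03 and 0.04 FPKM against 14.4 ± 0.703 and 35.3 ± 2.81 FPKM in xHet embryos.

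Lists that did not pass had adjusted p from 0.120 to 0.976: integrated stress response, maternal decidua, trophoblast, cell cycle, neural progenitor, yolk sac endoderm, somite and muscle, posterior Hox, maternally expressed imprinted genes and the DNA methylation machinery. In the trophoblast list Hand1 (9.03 ± 0.190 and 12.6 ± 1.59 FPKM), Krt18 (22.3 ± 1.26 and 31.5 ± 5.47 FPKM) and Krt8 (28.7 ± 2.66 and 40.8 ± 7.43 FPKM) passed adjusted over the list alone and 0 over all genes. Only 6 of the 18 genes of this list were measured, 4 higher and 2 lower. Prl3b1 was among the lower ones, at 2.06 ± 0.995 and 1.22 ± 0.922 FPKM, so the list does not show placental cells carried along. Of the posterior Hox genes Hoxd11 stood at 3.72 ± 0.348 and 5.77 ± 1.64 FPKM and Hoxb7 at 11.7 ± 0.731 and 8.88 ± 1.66 FPKM. The test was on the lower side while the median log2 change was above 0 for the methylation machinery (0.07), yolk sac endoderm (0.11) and somite and muscle genes (0.10). The medians of the methylation machinery and cell cycle lists changed sign under rescaling. Without xHet embryo 1, 4 lists passed.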

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

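The tests on the neighbours of Peg10 and on its parental group, those of scaling and of chromosomes for Alad, Rec8 and 4933404O12Rik, that of scaling for xHomo embryo 3 and the counts over other splits were chosen only after the results were seen. Among 155 values examined over the 10 xHomo embryos, 34 had 1 embryo standing far from the rest. Its gap to the nearest value was past the 95% critical value of Dixon for 10 samples, on log2(FPKM+1) or the measure itself. Chance gives about 1 in 20, and 21 of the 34 were in xHomo embryo 3. The flagged Meg3, Rian, Mirg, Nnat, Igf2r and Mest had been named for their large SD over these same embryos. The rate of 1 in 20 does not hold for genes so chosen.

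In xHomo embryo 3 the distant values were Cdkn1c at 192 FPKM on the high side and, on the low side, Igf2r at 17.8, Igf2 at 312, Tet3 at 4.80, Tie1 at 6.35, Plvap at 18.8, Cdh5 at 12.3, Cd68 at 2.20, Hoxb7 at 5.11, Pon3 at 1.25 and Dio3 at 1.21 FPKM. Its median log2 difference from the xHet mean was -0.49 for paternally and -0.39 for maternally expressed imprinted genes, -0.38 for the DNA methylation machinery, -1.07 for yolk sac endoderm, -1.24 for endothelium, -0.18 for p53 targets and -0.27 for immediate early genes. It had 12 imprinted departures, 11730 genes at 1 FPKM or more and a size factor of 0.790, all apart from the other 9. Elsewhere, Meg3, Rian and Mirg were 0.69, 3.18 and 1.17 FPKM in xHomo embryo 7, Nnat 27.3 FPKM in 5, and Mest 296, Copg2 41.9, Hoxa10 11.96 and Cdkn1a 8.39 FPKM in 9. Zfp566 at 7.81, Cryab at 5.27 and Hist1h2bb at 15.2 FPKM stood apart in xHomo embryo 1, Nefm at 4.01 FPKM in 2 and Mir483 at 115 FPKM in 10.

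The near-absence of Peg10 and Sgce in xHomo embryos 1, 7, 8, 9 and 10 was set against 2 technical explanations. Reads missing over the whole region would lower the neighbours Col1a2, Casd1, Ppp1r9a and Pon3 within 0.5 Mb, but the lowest of the 5 embryo medians over these 4 genes was -0.010 log2 units, which argues against it. A poor library would drop other genes of like expression as far, and at most 0.50% of 200 such genes (1 gene, LOC100861572, chosen after its values were seen) fell that far in any of the 5 embryos, which argues against that too. The parental genotype group, with 5 of 10 xHomo and 0 of 3 xHet embryos below 2-fold, stays open, since Fisher's exact test gave p = 0.231 (two-sided) and 3 xHet embryos are too few to decide. That test takes embryos as independent, but litters and batches are not in the labels. The same 5 embryos had hypoxia list medians of 0.52 to 1.55 log2 units above the xHet mean, against -0.29 to 0.08 in the other xHomo embryos. A litter or batch shared by these 5 embryos could not be tested. A changed imprint inherited at the domain of Peg10 and Sgce by single embryos is a hypothesis that was not tested, and neither was a genetic variant.

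The tight rise of Alad, Rec8 and 4933404O12Rik kept a log2 change of at least 0.66 under TPM rescaling, median-of-ratios scaling and quantile normalization. Size factors were 0.953 to 1.01 in xHet embryos. In xHomo embryos they were 0.974 to 1.11, apart from 0.790 in embryo 3. Rescaling by such factors could hardly move changes this large, so the test adds little. The small factors themselves argue against the scaling of the libraries as the cause. The 3 genes lie on 3 chromosomes, which argues against 1 linked segment. For Alad alone, extra copies of its segment of chromosome 4 stay open: of 4 neighbours, all outside the rule for named genes, Hdhd3 (62160088 to 62163234) had a log2 change of 0.70 (limma adjusted p = 0.0341 over the neighbours and 0.486 over all genes) and was above all xHet embryos in 9 of 10 xHomo embryos. In xHomo embryo 9 Hdhd3 was 1.25 FPKM, below all xHet embryos, while Alad was 56.9 FPKM, and Pole3, Rgs3 and Wdr31 had log2 changes of 0.28, 0.09 and 0.10 that did not pass. A batch that goes with the groups and the parental genotype stay open as untested, since the labels give no batch.

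The departure of xHomo embryo 3 from all other samples was set against RNA fragmentation and library scaling. Genes in the top quintile of locus length minus those in the bottom quintile deviated by a median of -0.32 log2 units there. This lies outside the -0.14 to 0.11 of the other 12 samples, as fragmented RNA with loss of long genes would give. Locus length is the genomic span, can join genes and is not transcript length, which was not available, so fragmentation is left undecided. Scaling by 1 factor per library would move long and short genes nearly alike, so the difference itself argues against such scaling as the whole cause. Median-of-ratios scaling uses 1 such factor and could hardly change the difference, so its value of -0.34 (lowest other sample -0.14) adds nothing. After quantile normalization, which is not 1 factor, the difference was -0.23. That is below the lowest other sample (-0.11) by more than the SD, which also argues against scaling as the whole cause. The share of genes at least 1 log2 unit away was 10.2% as deposited, 5.30% and 4.13% after these rescalings, against 4.14% and 4.05% in the highest other xHomo embryo. No biological explanation was tested, since the labels set this embryo apart in no way.

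Other splits of the 13 samples into 3 and 10 were counted in 100 draws that include the real one. For the 3 genes and the 12 lists 1 draw, the real one, reached as many, the highest others being 2 genes and 10 lists. This share argues against chance for these numbers with all 13 samples but does not exclude it, since the margin was small. The count was also chosen after the results were seen. Only 1 gene passed without xHet embryo 2 or 3 and 4 lists without xHet embryo 1, within the range of the other splits. At an unadjusted p under 0.05 in limma the real split gave 1193 genes, and some other draws gave more, up to 2519. Nor can chance be excluded for any single gene or list. The exact permutation test per gene passed 0 genes, and 0 lists passed with an estimated correlation. For the 2779 genes with array weights chance cannot be excluded, since 14 draws reached as many and the highest other gave 5784. For imprinted genes the real count was 0, which all 100 draws reach by construction, and the highest other was 6, so this count decides nothing.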

How the results depend on the processing

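Some of the settings below, named as such, were chosen after seeing the data. The depth behind each FPKM is unknown, which limits low genes most, and causes of changed calls were not tested. The 3 genes became 11 with no filter (3 higher and 8 lower, 19526 genes), 1 at a mean FPKM of at least 5 (fewer genes tested), 6 with TPM rescaling (5 higher and 1 lower), 5 with quantile normalization, 1 with the Xist covariate, 2779 with array weights, 0 in the exact permutation test per gene, and 8 (7 higher and 1 lower) without xHomo embryos 3 and 9 (added after seeing the data). Leaving out 1 embryo gave 1 to 11 genes and 4 to 12 lists. Of imprinted genes 14 passed with array weights and 0 under the other settings. List tests passed 6 lists with the Xist covariate and 3 on replicates 1 to 3 alone (added after seeing the data).

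Replicate numbers 1 to 3 are shared, but deviations of same-numbered samples correlated at -0.065, -0.040 and -0.038 and no sample correlated best with its own number, so they do not pair the embryos. With the replicate number as a block 1 gene, lower in xHomo, and 4 lists passed, and the medians were -0.23 for paternally and -0.066 (turned) for maternally expressed imprinted genes. The blocked signs of Airn (-0.23), Tet2 (-0.26), Tet3 (-0.20) and Igf2 (-0.19) turned, with the same values without the block.

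The median of paternally expressed genes was 0.00024 with no filter and 0.018 with the Xist covariate, both turned, and passed at -0.16 with median-of-ratios scaling and -0.14 with quantile normalization; leaving out 1 embryo moved neither median across the threshold. The spread of imprinted genes fell to percentile 84.2 with the median absolute deviation and was 99.7 or higher otherwise. The difference in imprinted departures per embryo passed at 3.33 at a mean FPKM of at least 5, 3.50 with median-of-ratios scaling, 3.40 with quantile normalization and 2.58 without xHomo embryos 3 and 9 (added); leaving out 1 embryo gave 2.80 to 4.60 with exact permutation p from 0.0091 (without xHomo embryo 3) to 0.409 (without xHet embryo 1). Pairs past the threshold numbered 1 with a pseudocount of 0.1 and 0 to 1 on leaving out 1 embryo.

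Of 65 named genes 7 changed sign somewhere, none of them called. Mest was 0.23 with the Xist covariate and 0.13 without xHomo embryos 3 and 9; Tet1 0.050 with array weights; Tet2 -0.053 with TPM rescaling, -0.023 with median-of-ratios scaling, -0.0052 with quantile normalization and -0.077 with the Xist covariate; Tet3 -0.016 with TPM rescaling; Igf2 -0.046 with quantile normalization. Leaving out 1 embryo gave -0.54 to 1.25 for Airn, -0.47 to 0.060 for Igf2r, -0.22 to 0.036 for Mest and -0.061 to 0.12 for Tet2.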

Other observations

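The values per embryo here were chosen only after the results were seen, and no tests were run on the embryos so grouped; the group means of these genes and of their list were tested in limma and camera. Hypoxia response genes were high in xHomo embryos 7, 8, 9 and 10, which are among the 5 embryos with low Peg10. Hk2, a hexokinase gene of glycolysis, was 49.2, 47.8, 50.7 and 46.3 FPKM in these embryos and 27.9 FPKM in xHomo embryo 1, against 15.8 to 20.5 FPKM in the xHet embryos and 12.9 to 22.5 FPKM in the other 5 xHomo embryos. Higd1a, a mitochondrial gene induced by low oxygen, was 51.98, 60.5, 56.3 and 43.8 FPKM in xHomo embryos 7 to 10 and 29.6 FPKM in xHomo embryo 1, against 19.12 to 23.1 FPKM in the xHet embryos and 17.1 to 27.3 FPKM in the others. Litters and the order of dissection are not in the labels.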
